A study of Mus musculus with 12 samples.

How the data were processed

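Total RNA of snap-frozen kidneys was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per mouse, in WT and KO mice at baseline and after ANG II infusion, with 3 arrays in each of 4 groups. The labels name RMA, a background correction, quantile normalization and summary of probes, as the processing of the submitters. The deposited values were on a linear scale as a ratio of each array to the probe set's own median over the 12 arrays. This was read from the values, since the division is not stated: the median over the arrays lay within 0.002 of 1 for 45099 of 45101 probe sets, and array medians ran from 0.986 to 1.014. The remaining 2 probe sets had values of 89.84 to 212.4. No pair of arrays held identical values.

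The ratios were put on the log2 scale, and 64 control probe sets were left out, so 45037 probe sets were tested. Of these 34945 carried 1 gene symbol, 932 several and 9160 none, and 9010 of the 18193 genes had more than 1 probe set. Gene symbols were those of the array annotation, and the order of genes along chromosomes was that of assembly GRCm38.p6.

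A linear model with a mean for each of the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, which left 8 residual degrees of freedom and gave 5.83 prior degrees of freedom. There were 5 comparisons, namely ANG II against baseline in WT and in KO, the difference of these responses, and KO against WT at baseline and under ANG II. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Standard errors are moderated. The replicate numbers of the labels were taken as names of samples and not as pairs.

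The comparisons, the gene lists, the rule for named genes and most alternatives were set before the data were examined, and 3 parts of that plan were changed once the values were seen to be ratios. The plan moderated the variances with a trend on mean intensity. Ratios keep no intensity, so the values reported come from limma without that trend, and the planned trend is given as an alternative. The plan took for each gene the probe set with the highest mean. In its place stands the probe set with the plainest name, that is a plain _at probe set before _a_at, _s_at and _x_at, and among equals the lowest number. A planned filter on dim probe sets was not run, and a filter on probe sets of low spread was added.

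Genes were named by 3 rules. The first took the receptor and renin-angiotensin genes, of which 5 were measured, while Ren1 and Ren2 had no probe set with 1 symbol and were not analysed here. The second took called genes whose groups did not overlap, the 12 largest rises and 12 largest falls in the WT response, 8 and 8 in each other comparison of 2 groups, and the 10 largest differences of the responses. The third took up to 4 called genes of each list, or 2 where none was called, and the text names part of these. Where a gene's probe sets were called in opposite directions, this is stated.

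There were 29 gene lists, 16 of pathways and 13 of cell types the kidney or adjacent tissue can hold. Each was tested against all other genes with camera at a preset correlation of 0.01, with 1 probe set per gene, and adjusted over the lists within a comparison. Camera with the correlation estimated for each list and fry, which tests whether a list moves on balance one way, were run beside it. Members called are counted over all probe sets tested and adjusted over the list alone.

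The alternatives tried were the variance trend, a fit to the 2 groups alone, quantile normalization again, arrays centred on a common median, 1 probe set per gene, the mean of a gene's probe sets, the replicate number as a block, array weights, the filter on low spread, and each of the 12 arrays left out in turn. The procedure was tested on simulated data with the design of the 12 arrays and changes in the WT response. Each probe set was drawn independently, with its spread from the fit to all 12 arrays and equal in all 4 groups. Of 50 probe sets changed by a log2 of 0.5 it called 25, and of 50 changed by 1 it called 50, while 9 unchanged probe sets of 45037 were called. The adjusted threshold depends on the share of probe sets that change. Far fewer were changed here than the 10876 called in the WT response, so these recovery counts do not carry over to the real data. All 5 lists shifted by 0.3 were called, and 0 of the 24 others. Since simulated genes were independent, this does not measure false list calls where members are correlated, as estimated for macrophage markers at 0.40. The number of arrays limits the precision, and signal over background cannot be read from ratios.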

Results

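Kidneys of wild-type (WT) mice and of mice lacking the AT1A angiotensin receptor (KO) were profiled without treatment (baseline) or once angiotensin II (ANG II) had been infused for 2 days at 1 ug/kg/min. Angiotensin II is the effector peptide of the renin-angiotensin system, and Agtr1a encodes its main receptor in the mouse kidney. There were 12 arrays, 3 in each of the 4 groups, and per the labels each array came from a separate male mouse of an F1 cross of C57BL6 and 129/SvEv. The arrays held 45037 probe sets other than controls, and 34945 of them carried 1 gene symbol, which gave 18193 genes. Each deposited value was the ratio of an array to that probe set's median over the 12 arrays, so changes between groups could be read but levels of different genes could not. The number of arrays, 3 per group, limits the precision of every value. Errors of log2 changes are moderated standard errors from 1 fit to all 12 arrays.

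The targeted gene was examined first. The single probe set of Agtr1a gave ratios of 1.36 to 1.40 in the WT baseline kidneys, 0.92 to 1.04 in the KO baseline kidneys, 0.96 to 1.00 in the WT ANG II kidneys and 0.92 to 1.05 in the KO ANG II kidneys. Agtr1a was lower in KO than in WT at baseline by a log2 change of -0.49 ± 0.08 (n = 3 per group, adjusted p = 0.00306, limma with Benjamini-Hochberg adjustment). Under ANG II the genotypes differed by -0.00 ± 0.08 (adjusted p = 0.98), because the WT ratio fell by 0.48 on the log2 scale during the infusion (adjusted p = 0.0012). Whether this probe set lies in the deleted part of the gene is not given in the sources used here, so it checks the genotype labels of the baseline kidneys only in part and those of the infused kidneys not at all.

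**Figure D1:**
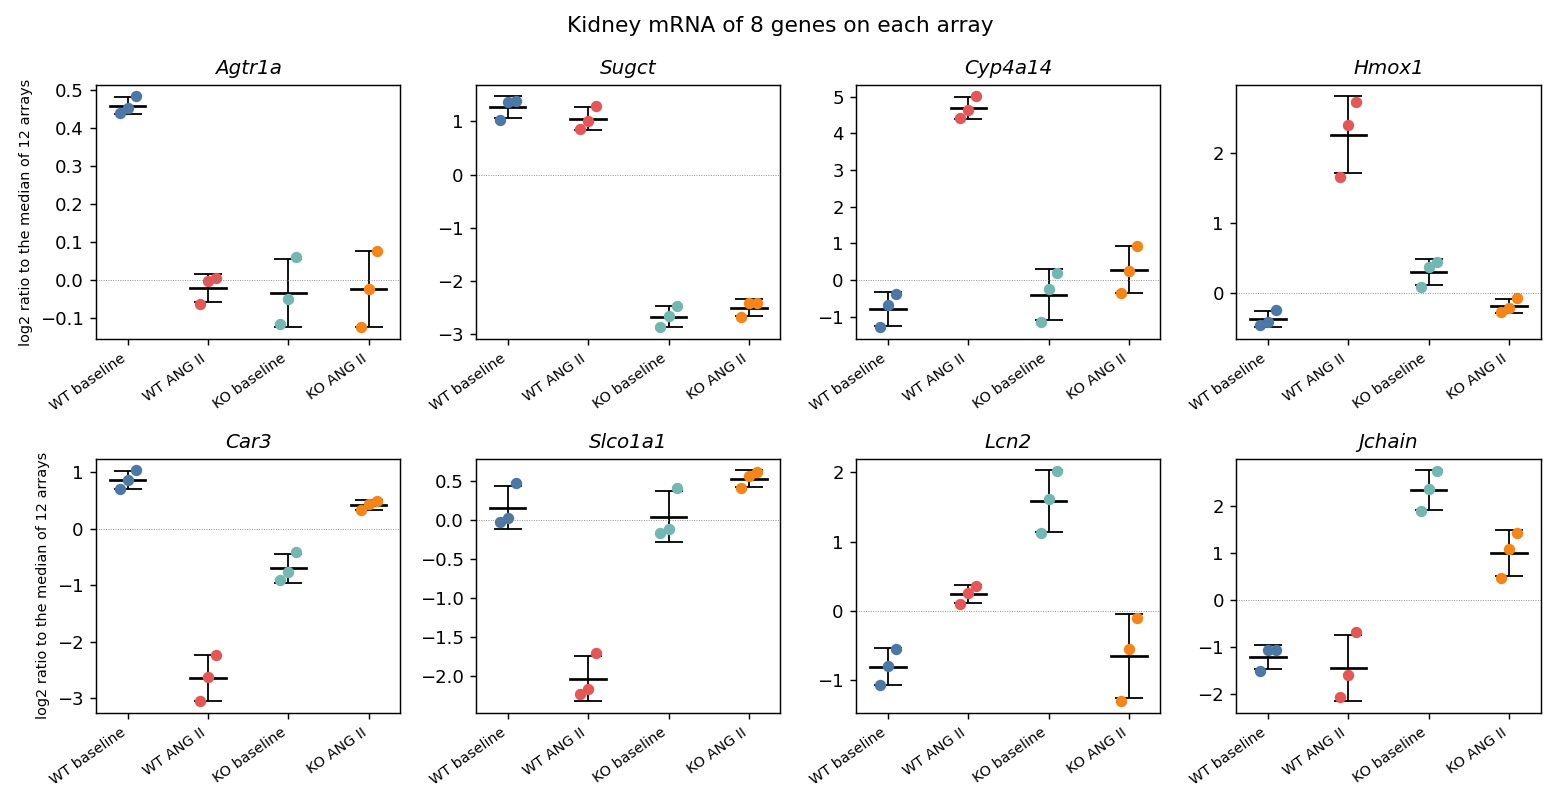
Log2 ratio to the median of the 12 arrays (vertical axes, a different range in each panel) for 8 genes in the 4 groups. Points are single arrays, and black lines and bars are the mean and SD of 3 arrays. Cyp4a14 and Hmox1 were high in the WT ANG II arrays and Lcn2 in the KO baseline arrays. Jchain was highest in the KO baseline arrays and was higher in all 6 KO arrays than in all 6 WT arrays. Sugct was lower in all 6 KO arrays than in all 6 WT arrays.

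The first comparison asked which kidney genes change with the infusion when the receptor is present. Cyp4a14, a cytochrome P450 that hydroxylates fatty acids, rose 44.7-fold in WT kidneys (log2 change 5.48 ± 0.35, n = 3 per group, adjusted p = 1.86e-06, limma with Benjamini-Hochberg adjustment). Serpina6, the corticosteroid-binding globulin, rose 7.99-fold (3.00 ± 0.34), Hmox1, which degrades heme, 6.25-fold (2.64 ± 0.20), and Depp1 6.12-fold (2.61 ± 0.40). The other genes among the 12 with the largest rises lay between log2 changes of 1.75 and 2.15, and they were Kynu, Pdk4, 2410006H16Rik, Tmem37, Hpd, Cp, Gldc and Igfbp1. Car3, a carbonic anhydrase, was 11.3-fold lower in infused than in baseline WT kidneys (-3.50 ± 0.17), and Ces1g, a carboxylesterase, 8.72-fold lower (-3.12 ± 0.26). The remaining 10 of the 12 largest falls lay between -1.87 and -2.47, and 5 of them encode transporters, namely Slc7a13, Mfsd2a, Slco1a1, Slc51a and Slc22a30. The others were Acsm3, 3110040M04Rik, the clock output gene Dbp, Gm32461 and Rnf180, of which Rnf180 had 1 of its 2 probe sets called in the other direction. In all, 10876 probe sets changed at an adjusted p under 0.05, of which 4888 rose and 5988 fell. For the Actb and Gapdh controls, 3' and 5' values were each relative to their own median over the arrays. Their difference is a sign of relative RNA quality and cannot show whether RNA was intact. On the log2 scale, 3' minus 5' was 0.036 to 0.067 in the WT ANG II arrays and -0.018 to -0.0074 in the WT baseline arrays. The SD of log2 ratios over probe sets was 0.27 to 0.34 and 0.16 to 0.18 in these groups. With a trend of the variance on the mean ratio, the calls of Slc7a13 (adjusted p = 0.0562) and Acsm3 (adjusted p = 0.107) ended. Quantile normalization of the deposited values gave 5704 changed probe sets, of which 1878 rose, while leaving out WT baseline replicate 1 gave 5773 and leaving out WT ANG II replicate 3 gave 6921.

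Among components of the renin-angiotensin system, 1 of 12 measured genes rose and 4 fell in WT kidneys (2 and 4 adjusted over the list alone). Ace, which makes angiotensin II, fell by 0.71 on the log2 scale (adjusted p = 0.000209), and Anpep, a peptidase that trims angiotensin peptides, fell by 0.75. Agt, the angiotensin precursor, rose by 0.58 ± 0.14 (adjusted p = 0.00939), a call that ended with quantile normalization (adjusted p = 0.0567). Agtr1b had a log2 change of 0.14 ± 0.11 and Agtr2 one of -0.11 ± 0.11, and neither was called. The list as a whole was not called against other genes (camera adjusted p = 0.132).

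Of 29 gene lists fixed before the data were examined, 7 were called in the WT response, 2 upward and 5 downward, and none of these calls held when the correlation between genes was estimated. Member counts are to be read against all 18193 genes, of which 1748 rose and 2644 fell in WT. Mineralocorticoid-responsive distal genes shifted upward (camera adjusted p = 0.0147, and adjusted p = 0.484 with an estimated correlation), with 5 of 19 members rising and 0 falling, the same numbers as when adjusted over the list alone. They included Sgk1, the kinase that stimulates sodium transport, at 0.87 ± 0.11, the sodium channel subunit Scnn1a at 0.67 ± 0.10, and Fkbp5 at 0.96 ± 0.19. Tubular injury genes also shifted upward (camera adjusted p = 0.0409, and adjusted p = 0.484 with an estimated correlation), with 9 of 23 rising and 2 falling (9 and 2 adjusted over the list alone). Besides Hmox1, the cell-cycle inhibitor Cdkn1a rose by 1.54 ± 0.21 and the fibrinogen chains Fga and Fgg by 1.35 ± 0.16 and 1.21 ± 0.19.

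Cholesterol synthesis genes shifted downward in WT kidneys, with 9 of 16 members falling and 2 rising (10 and 2 adjusted over the list alone; camera adjusted p = 0.000461, and adjusted p = 0.484 with an estimated correlation). Idi1 fell by 1.75 on the log2 scale, Dhcr7 fell by 1.10 and Cyp51 fell by 0.86. Of 14 genes of vitamin D, phosphate and calcium handling 5 fell and 0 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0431, and adjusted p = 0.484 with an estimated correlation), led by the phosphate transporter gene Slc34a3, which fell by 0.94. This list call ended with the replicate number as a block (camera adjusted p = 0.0563). Among interferon-stimulated genes 9 of 23 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.484 with an estimated correlation), with Usp18 at -0.78 ± 0.13 and Gbp2 at -0.68 ± 0.11. In oxidative phosphorylation 5 of 28 members fell and 2 rose, by either adjustment (camera adjusted p = 0.0431, and adjusted p = 0.585 with an estimated correlation). These 5 falls were close to the share of all genes that fell. Cycs, which encodes cytochrome c, fell by 1.05. The replicate number as a block ended the call of oxidative phosphorylation too (camera adjusted p = 0.0563). Macrophage markers shifted downward with 5 of 18 falling and 1 rising (8 and 1 adjusted over the list alone; camera adjusted p = 0.0431, and adjusted p = 0.585 with an estimated correlation). Cd68 at -0.67 ± 0.20 was among them, and its call ended with quantile normalization (adjusted p = 0.176), without WT ANG II replicate 2 or 3 (adjusted p = 0.0636 and 0.0914) and without WT baseline replicate 1 or 2 (adjusted p = 0.141 and 0.0984).

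In the second comparison, the same infusion was given to mice without the receptor. Igfbp2, a binding protein of insulin-like growth factors, was 5.18-fold lower in infused than in baseline KO kidneys (log2 change -2.37 ± 0.29, n = 3 per group, adjusted p = 0.000315, limma with Benjamini-Hochberg adjustment). Lcn2, an injury marker of tubule cells, was 4.73-fold lower (-2.24 ± 0.26), Lyz2, the lysozyme of macrophages, 4.46-fold lower (-2.16 ± 0.33), and the transcription factor Egr1 4.12-fold lower (-2.04 ± 0.38). Slc7a12 (-2.21), Smoc2 (-1.95), the activin subunit Inhbb (-1.78) and the chemokine Cxcl1 (-1.70) completed the 8 largest falls, and the call of Slc7a12 ended without KO baseline replicate 2 (adjusted p = 0.0633). The largest rises were those of S100a9 (1.84 ± 0.41) and S100a8 (1.58 ± 0.44), calcium-binding proteins of neutrophils, followed by Akr1c18 (1.56), Smcp (1.34), Angptl7 (1.33), Odc1, the first enzyme of polyamine synthesis (1.31), Sfxn1 (1.28) and Ccl28 (1.18). The S100a8 call ended with only the 2 groups compared (adjusted p = 0.0567), without KO ANG II replicate 1 or 3 (adjusted p = 0.1 and 0.0932) and without KO baseline replicate 1, 2 or 3 (adjusted p = 0.0984, 0.0871 and 0.076). In all, 4465 probe sets changed, 1622 upward and 2843 downward. The SD of log2 ratios over probe sets was 0.165 to 0.196 in the KO ANG II arrays and 0.222 to 0.262 in the KO baseline arrays. The count was 2069 without KO ANG II replicate 3, 2619 without KO ANG II replicate 2, and 2678, 2171 and 2969 without KO baseline replicates 1, 2 and 3, and it was 6962 with array weights.

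In KO kidneys 13 gene lists were called, 2 upward and 11 downward, and none with an estimated correlation. Among all 18193 genes 779 rose and 1042 fell. Of 26 immediate early genes 14 fell and 1 rose (17 and 2 adjusted over the list alone; camera adjusted p = 8.26e-12, and adjusted p = 0.0585 with an estimated correlation). Fos fell by 1.67, Egr2 fell by 1.37 and Zfp36 fell by 1.21. Of 18 macrophage markers 10 fell and 1 rose (13 and 2 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation), among them Ctss (-1.54 ± 0.22) and the complement gene C1qb (-1.35 ± 0.19). In the tubular injury list 11 of 23 fell and 0 rose (12 and 2 adjusted over the list alone; adjusted p = 0.0585 with an estimated correlation), including the hyaluronan receptor Cd44, which fell by 1.62. Of 30 matrix and fibrosis genes 11 fell and 0 rose (15 and 1 adjusted over the list alone; adjusted p = 0.201 with an estimated correlation), with Ccn2 at -1.45 ± 0.18 and Mgp at -1.34 ± 0.23. Interferon-stimulated genes fell in 11 of 23 cases with 0 rising (13 and 1 adjusted over the list alone; adjusted p = 0.0585 with an estimated correlation). Inflammatory cytokine and adhesion genes fell in 9 of 26 with 0 rising (9 and 1 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation), with Cxcl1 as above. Oxidative stress genes fell in 7 of 23 cases and 1 rose (9 and 2 adjusted over the list alone; adjusted p = 0.0585 with an estimated correlation), led by Gsta2 (-1.20 ± 0.12) and Nqo1 (-1.13 ± 0.13).

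Markers of several other cell types shifted downward in KO kidneys as well. Among markers of principal cells of the collecting duct 5 of 13 fell (7 adjusted over the list alone), and among those of podocytes 4 of 12 (5 adjusted over the list alone). Both lists had adjusted p = 0.0585 with an estimated correlation. Of 16 endothelial markers 5 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.252 with an estimated correlation). Of 15 markers of vascular smooth muscle, mesangium and juxtaglomerular cells 4 fell (5 adjusted over the list alone; adjusted p = 0.201 with an estimated correlation). Plce1 in podocytes (-0.67 ± 0.10), Vwf in endothelium (-1.23 ± 0.19) and Rgs5 in vascular cells (-0.78 ± 0.12) led or were near the top of their lists. The 2 lists called upward were markers of the distal convoluted tubule, with 3 of 13 rising (5 adjusted over the list alone; adjusted p = 0.408 with an estimated correlation), and oxidative phosphorylation. Pvalb led the first at 0.84 ± 0.13. In the second 1 of 28 members rose by either adjustment, Uqcrc2 at 0.53 ± 0.07 (adjusted p = 0.522 with an estimated correlation).

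**Figure D2:**
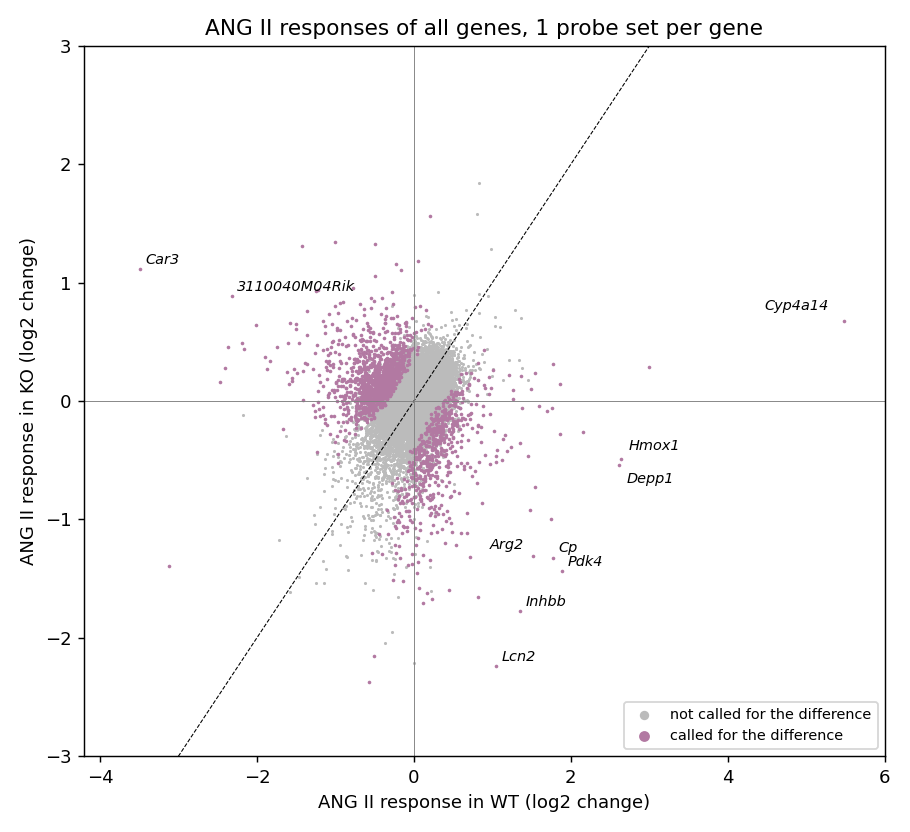
Log2 change with ANG II in WT kidneys (horizontal axis) against that in KO kidneys (vertical axis), 1 point for each of 18193 genes, with genes called for the difference of the responses in purple, the line of equal responses dashed, and the 10 genes with the largest differences named. Cyp4a14 rose by 5.48 in WT, and Lcn2 fell by 2.24 in KO.

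The third comparison tested whether the change with the infusion differed between the genotypes. It shares the KO baseline arrays with the KO response and the baseline comparison, so a shift of these arrays enters each of them. For immediate early genes the median log2 was 0.20 in the WT response and -0.71 in the KO response. It was -0.77 for the difference and 0.67 for KO minus WT at baseline. The response of Cyp4a14 was 27.9-fold smaller in KO than in WT kidneys (difference of log2 changes -4.80 ± 0.49, n = 3 per group, adjusted p = 7.21e-05, limma with Benjamini-Hochberg adjustment). The response of Car3 differed in the other direction by 4.61 ± 0.24, a call that ended with a trend of the variance on the mean ratio (adjusted p = 0.0744), and that of 3110040M04Rik by 3.20 ± 0.43. Pdk4, a brake on glucose oxidation (-3.32), Lcn2 (-3.29), Depp1 (-3.15), Inhbb (-3.13), Hmox1 (-3.13), the copper carrier Cp (-3.09) and Arg2 (-2.83) made up the rest of the 10 largest differences. Ace differed by 0.97 ± 0.13 and Agtr1a by 0.49 ± 0.11, whereas Agt (-0.46 ± 0.19), Agtr1b (-0.01 ± 0.16) and Agtr2 (0.24 ± 0.15) were not called. A second probe set of Ace differed by 0.58 ± 0.13 and was called. In KO the probe sets of Ace changed by 0.26 and -0.25, and neither was called. Agtr1a, the targeted gene, had a KO change of 0.01 ± 0.08, so its difference mirrors its fall in WT. In all, 4404 probe sets had responses that differed, 2565 higher and 1839 lower in KO. The count was 2867 with quantile normalization, 2484 without KO ANG II replicate 3 and 2868 without WT baseline replicate 3.

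For the difference of the responses 16 lists were called, 3 upward and 13 downward, and none with an estimated correlation. Among all 18193 genes 1265 had higher and 599 lower responses in KO. Tubular injury genes had lower responses in KO in 12 of 23 cases and a higher one in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.0797 with an estimated correlation), with Cdkn1a at -2.26 ± 0.30 and Cd44 at -1.79 ± 0.28. Immediate early genes did so in 13 of 26 cases (16 adjusted over the list alone; adjusted p = 0.0797 with an estimated correlation), with Dusp1 at -1.42 ± 0.15 and Btg2 at -1.39 ± 0.22. Mineralocorticoid-responsive genes did so in 4 of 19 (7 adjusted over the list alone; adjusted p = 0.164 with an estimated correlation), and Sgk1, which rose in WT, fell by 0.86 in KO, a difference of -1.73 ± 0.15. Cholesterol synthesis genes had higher responses in KO in 6 of 16 cases (6 adjusted over the list alone; adjusted p = 0.249 with an estimated correlation), with Idi1 at 2.20 ± 0.22. Proximal tubule markers were higher in 9 of 29 and lower in 3 (10 and 5 adjusted over the list alone; adjusted p = 0.249 with an estimated correlation), led by the transporters Slc7a13 (2.63 ± 0.52), Slc22a7 (2.17 ± 0.29) and Slc34a3 (1.76 ± 0.15). The call of Slc7a13 ended with a trend of the variance on the mean ratio (adjusted p = 0.216).

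Despite these differences, 394 probe sets rose in both genotypes, where 176 would be shared by independent lists of the same sizes, and 813 fell in both, where independent lists would share 378. Another 147 rose in WT and fell in KO (309 for independent lists), and 247 fell in WT and rose in KO (216 for independent lists). Across all probe sets, which are not independent replicates, the responses correlated with a Pearson r of 0.235 and a Spearman rho of 0.284. The responses shared no arrays. At an unadjusted p under 0.01 and at least 1.5-fold in place of the adjusted p, 20 rose and 227 fell in both, against 2.16 and 43.5 for independent lists. At that threshold 41 rose in WT and fell in KO and 51 did the reverse, against 14.8 and 6.35 for independent lists, so that calls in opposite directions also exceeded the independent value.

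The fourth comparison asked what the loss of the receptor changed without infusion. KO baseline kidneys had higher transcripts of 3 antibody genes than WT baseline kidneys. Jchain, which joins secreted antibodies, was 11.6-fold higher (log2 change 3.53 ± 0.31, n = 3 per group, adjusted p = 5.8e-05, limma with Benjamini-Hochberg adjustment), and Igkv8-30 and Igha were 10.7-fold and 9.65-fold higher (3.42 ± 0.36 and 3.27 ± 0.23). Ighm, another immunoglobulin gene, looked up after its values were seen, differed by 0.15 ± 0.10 on 1 of its 11 probe sets and was not called (adjusted p = 0.393). Its other probe sets are not reported here, and whether this one detects its transcript cannot be read from ratios. Cd44, Lyz2, D17H6S56E-5, Lcn2 and the calcification inhibitor Mgp were higher by log2 changes of 2.37 to 2.43. Sugct was 15.4-fold lower in KO (-3.94 ± 0.14) and the glutathione peroxidase Gpx6 8.5-fold lower (-3.09 ± 0.18), and both lie on the chromosome that carries Agtr1a. Sugct had ratios of 0.136 to 0.188 in the 6 KO arrays and of 1.81 to 2.62 in the 6 WT arrays, and Gpx6 of 0.196 to 0.402 and of 1.60 to 2.41, so that both genes separated the genotypes on every array. Only 1 of the 2 probe sets of Sugct was called lower at baseline. The other large falls were those of Car3 (-1.56), Cyp27b1, the enzyme that activates vitamin D (-1.42), Clec2h (-1.41), Slc22a29 (-1.22), the clock repressor Nr1d1 (-1.18) and 4931408D14Rik (-1.09). With a trend of the variance on the mean ratio, the calls of Sugct (adjusted p = 0.86), Gpx6 (adjusted p = 0.19) and Car3 (adjusted p = 0.421) ended. That of Cyp27b1 ended without KO baseline replicate 1, 2 or 3 (adjusted p = 0.0599, 0.0768 and 0.0727) and without WT baseline replicate 2 or 3 (adjusted p = 0.0659 and 0.123). In all, 2936 probe sets differed, 2193 higher and 743 lower in KO. The SD of log2 ratios over probe sets was 0.222 to 0.262 in the KO baseline arrays and 0.164 to 0.18 in the WT baseline arrays. The count was 1107 without WT baseline replicate 3, 1602 without WT baseline replicate 2, 1909 and 1243 without KO baseline replicates 1 and 2, and 4849 with array weights.

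Among all 18193 genes 822 were higher and 372 lower in KO at baseline. In this comparison 13 lists were called, 12 higher in KO and 1 lower, and 3 of the calls held with an estimated correlation. Tubular injury was the first (10 of 23 higher and 0 lower, 12 and 0 adjusted over the list alone). Immediate early genes (14 of 26 higher and 0 lower, 18 and 1 adjusted over the list alone) and interferon-stimulated genes (13 of 23 higher and 0 lower, 17 and 0 adjusted over the list alone) were the others. Each of these 3 had adjusted p = 0.036 with an estimated correlation. Vcam1 at 1.52 ± 0.14, Egr1 at 2.18 ± 0.38, Fos at 1.96 ± 0.33, Oasl2 at 1.13 ± 0.15 and Gbp2 at 1.02 ± 0.11 were among their members. Of 18 macrophage markers 11 were higher and 0 lower (14 and 1 adjusted over the list alone; adjusted p = 0.0763 with an estimated correlation), with a median log2 change of 0.99, and Ctss, C1qb and Mpeg1 at 1.71 ± 0.22, 1.66 ± 0.19 and 1.48 ± 0.17. Lymphocyte and neutrophil markers did not shift with them (median -0.12, 1 of 12 higher, camera adjusted p = 0.943). Matrix genes were higher in 13 of 30 cases and lower in 0 (21 and 1 adjusted over the list alone; adjusted p = 0.112 with an estimated correlation), with Tgfbi at 1.56 ± 0.17 and Ccn2 at 1.34 ± 0.18. Cytokine and adhesion genes were higher in 10 of 26 and lower in 0 (14 and 1 adjusted over the list alone; adjusted p = 0.0844 with an estimated correlation), with Cxcl1 at 2.05 ± 0.20.

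Endoplasmic reticulum stress and heat shock genes were higher in 7 of 24 cases and lower in 0 (9 and 1 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation), with Hspb1 at 1.24 ± 0.13. Of 16 endothelial markers 3 were higher (5 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation), and of 12 podocyte markers 3 (7 adjusted over the list alone; adjusted p = 0.0784 with an estimated correlation). Of 13 principal cell markers 3 were higher (4 adjusted over the list alone; adjusted p = 0.0763 with an estimated correlation), and of 15 vascular cell markers 5 (6 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation). The medians of these lists were 0.18, 0.31, 0.24 and 0.19. The fatty acid oxidation list was called with 1 of 29 members higher, Pdk4 at 1.75 ± 0.33, and a median of 0.06 (1 adjusted over the list alone; adjusted p = 0.513 with an estimated correlation). Cholesterol synthesis was the list called lower, with 3 of 16 members lower (7 adjusted over the list alone; adjusted p = 0.202 with an estimated correlation), Dhcr7 at -0.55 ± 0.11.

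**Figure D3:**
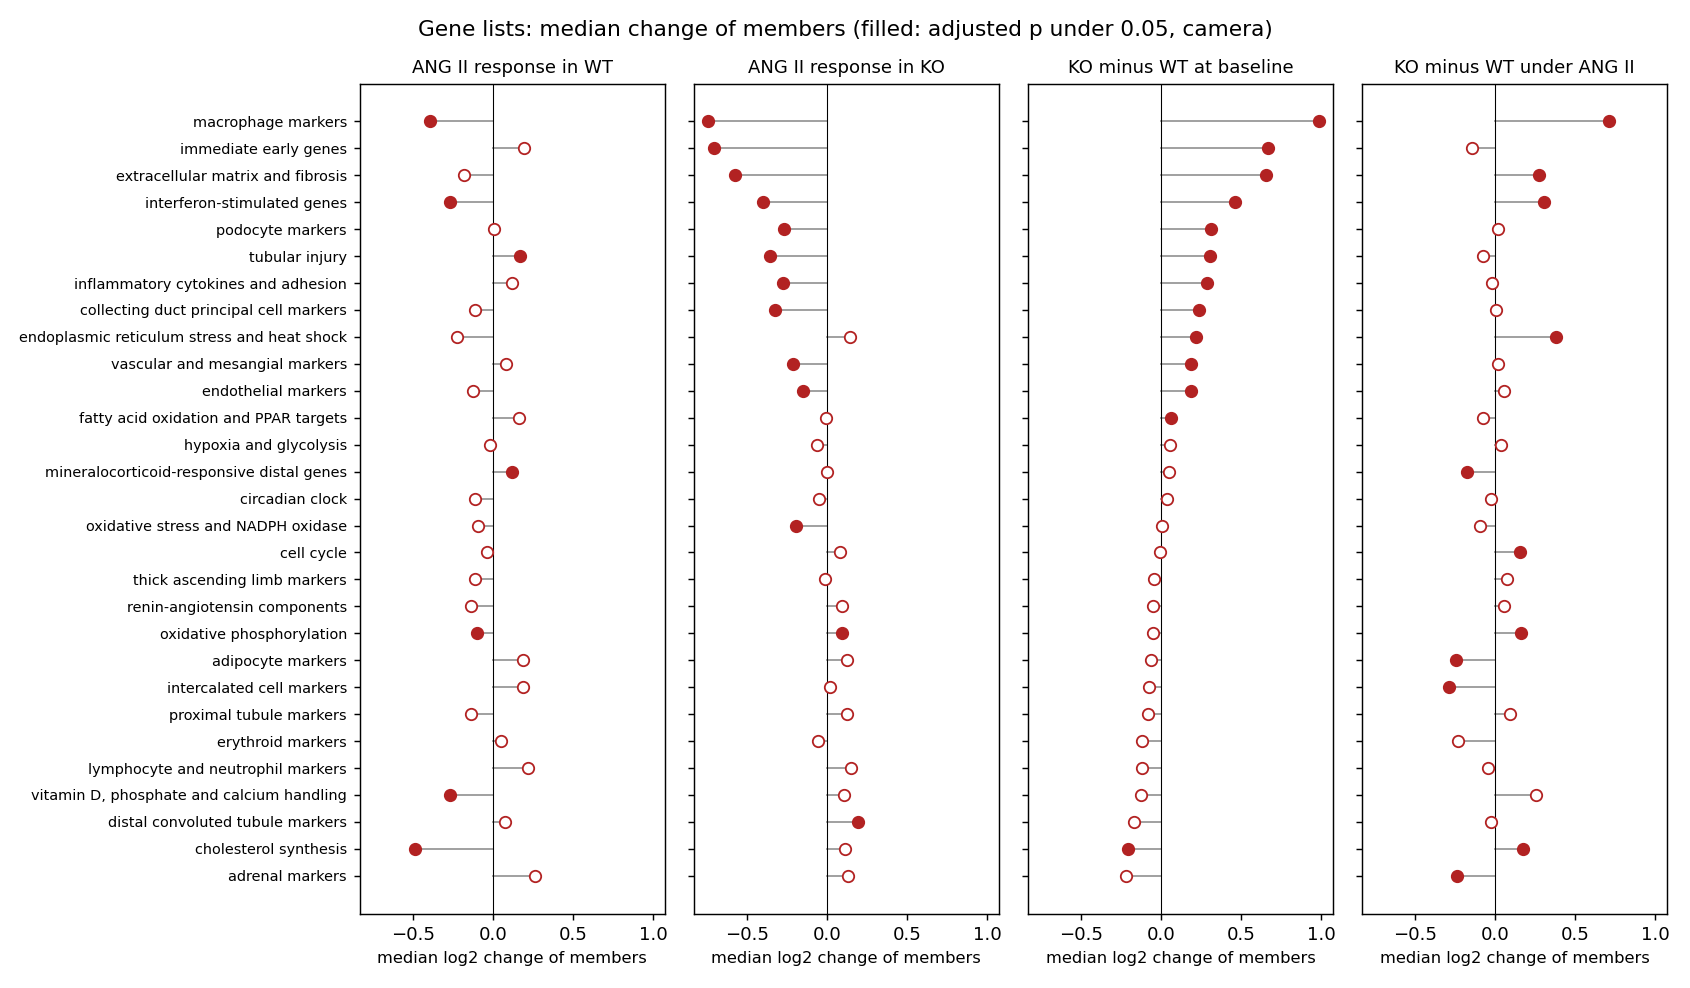
Median log2 change of the measured members of each of the 29 gene lists (horizontal axes) in the 4 comparisons of 2 groups. Filled points mark lists with a camera adjusted p under 0.05. Macrophage markers had medians of -0.39, -0.74, 0.99 and 0.71 from left to right.

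The fifth comparison set the genotypes against each other during the infusion. Cyp4a14 was 21.2-fold lower in KO than in WT kidneys (log2 change -4.41 ± 0.35, n = 3 per group, adjusted p = 3.63e-06, limma with Benjamini-Hochberg adjustment), Igfbp1, a binding protein of insulin-like growth factors, 12.2-fold lower (-3.61 ± 0.26). Sugct and Gpx6 were again lower, by -3.56 ± 0.14 and -3.04 ± 0.18. Serpina6 (-3.01), Depp1 (-2.65), Kynu (-2.54) and Hmox1 (-2.46) completed the 8 largest falls. Car3 and 3110040M04Rik were both 8.27-fold higher in KO (3.05 ± 0.17 and 3.05 ± 0.30), followed by Acsm3 (2.78), Odc1 (2.67), Rnf180 (2.62), Ces1g (2.58), Slco1a1 (2.57) and Slc51a (2.56). Jchain, higher in KO at baseline, had ratios of 1.38 to 2.68 in the KO ANG II arrays and 0.24 to 0.622 in the WT ANG II arrays. Ace was higher in KO by 0.96 ± 0.09 and Agt lower by -0.51 ± 0.14, the latter adjusted p = 0.0193. The Agt call ended with quantile normalization (adjusted p = 0.0861), without KO ANG II replicate 1 (adjusted p = 0.0561) and without WT ANG II replicate 2 or 3 (adjusted p = 0.052 and 0.0585). With a trend of the variance on the mean ratio the calls of Sugct (adjusted p = 0.834), Gpx6 (adjusted p = 0.12), Car3 (adjusted p = 0.0615) and Acsm3 (adjusted p = 0.0751) ended. In addition 1 of the 2 probe sets each of Sugct and Rnf180 was called in the other direction. In all, 8934 probe sets differed, 5254 higher and 3680 lower in KO. The 3' minus 5' log2 difference of the relative Actb and Gapdh values was 0.00023 to 0.011 in the KO ANG II arrays and 0.036 to 0.067 in the WT ANG II arrays. The SD of log2 ratios over probe sets was 0.165 to 0.196 and 0.268 to 0.342 in these groups. Quantile normalization gave 4063, of which 2879 were higher, and the 2 groups alone gave 4991. The count was 5021 without KO ANG II replicate 1, 5103 without KO ANG II replicate 3 and 5574 without WT ANG II replicate 3.

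During the infusion 11 lists were called, 7 higher and 4 lower in KO, and none with an estimated correlation (adjusted p = 0.49 for each except matrix genes, at adjusted p = 0.62 with an estimated correlation, and cholesterol synthesis, at adjusted p = 0.543 with an estimated correlation). Among all 18193 genes 2495 were higher and 1432 lower in KO. Macrophage markers were higher in 10 of 18 cases and lower in 1 (13 and 1 adjusted over the list alone), with C1qc at 0.88 ± 0.20. Interferon-stimulated genes were higher in 12 of 23 cases (13, and 1 lower, adjusted over the list alone), with Oasl2 at 0.92 ± 0.15. Matrix genes were higher in 10 of 30 with 1 lower (12 and 1 adjusted over the list alone), with Fbln5 at 1.67 ± 0.18. Endoplasmic reticulum stress and heat shock genes were higher in 13 of 24 and lower in 1 (14 and 2 adjusted over the list alone), with Hsph1 at 1.24 ± 0.17. Cholesterol synthesis genes were higher in 5 of 16 and lower in 1 by either adjustment, with Idi1 at 1.79 ± 0.15. Cell cycle genes were higher in 6 of 39 cases by either adjustment, close to the share of all genes, with Mki67 at 0.75 ± 0.13. Oxidative phosphorylation genes were higher in 6 of 28 (11 adjusted over the list alone), with Cycs at 0.99 ± 0.10. The lists lower in KO were mineralocorticoid-responsive genes (4 of 19, 7 adjusted over the list alone), with Sgk1 at -0.85 ± 0.11, and intercalated cell markers (3 of 13, 5 adjusted over the list alone), with Rhcg at -0.40 ± 0.08. They were joined by adipocyte markers (1 of 9, Plin4 at -1.02 ± 0.18) and adrenal markers (1 of 11, Mc2r at -0.40 ± 0.11), by either adjustment. These 2 counts were close to the share of all genes lower in KO. The call of Mc2r ended with the 2 groups alone (adjusted p = 0.0517), with quantile normalization (adjusted p = 0.0766), without KO ANG II replicate 1 or 3 (adjusted p = 0.0581 and 0.079) and without WT ANG II replicate 3 (adjusted p = 0.0829).

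Several lists were called in none of the 4 comparisons of 2 groups. Proximal tubule markers went both ways in WT (5 of 29 rose and 11 fell, 5 and 13 adjusted over the list alone; camera adjusted p = 0.109), with the sulfate transporter gene Slc13a1 rising by 1.49 ± 0.17 and Slc22a7 at -1.83 ± 0.21. Hypoxia and glycolysis genes did so too (3 of 22 rose and 6 fell, 4 and 8 adjusted over the list alone; camera adjusted p = 0.346). Of 18 clock genes 4 rose and 4 fell in WT (5 and 4 adjusted over the list alone; camera adjusted p = 0.882), with Cry1 at 1.70 ± 0.28, Nfil3 at 1.60 ± 0.19 and Nr1d1 at -1.23 ± 0.17. Thick ascending limb markers had 1 of 11 rising and 2 falling in WT by either adjustment (camera adjusted p = 0.344), and erythroid markers 1 of 3 rising by either adjustment, Alas2 at 1.38 ± 0.16 (camera adjusted p = 0.346). The fatty acid oxidation list was called at baseline, though not with an estimated correlation (camera adjusted p = 0.513), and was not called in the WT response. In WT 8 of 29 members rose and 2 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.067). Acot3 rose by 1.21 ± 0.15, with the fatty acid transporter gene Cd36 at -1.26 ± 0.16.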

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

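The tests on mislabelled genotypes, the share of tubule cells, exchanged treatment labels and the time of collection were chosen after the results were seen. The test of the difference of the responses called 4404 probe sets, which is what drew attention to the genes and lists that follow. Among genes named in the comparisons, those with the higher response in KO were, with the difference of log2 changes, Car3 4.61, 3110040M04Rik 3.20, Mfsd2a 2.82, Odc1 2.73, Acsm3 2.69, Slco1a1 2.68, Gm32461 2.66, Slc7a13 2.63, Slc51a 2.60 and Smcp 2.35. Next came Slc22a30 2.27, Idi1 2.20, Slc22a7 2.17, Rnf180 2.15, Angptl7 1.82, Slc34a3 1.76, Ces1g 1.73, Cyp27b1 1.71, Slc22a29 1.42 and Dhcr7 1.37. Next came Akr1c18 1.35, Pvalb 1.35, Fbln5 1.25, Nr1d1 1.22, Cd36 1.18, Cycs 1.14, Ccl28 1.13, Ace 0.97, Anpep 0.82 and Agtr1a 0.49. The last is the targeted gene, whose response was called only in WT. Those with the lower response in KO were Cyp4a14 -4.80, Pdk4 -3.32, Lcn2 -3.29, Depp1 -3.15, Hmox1 -3.13, Inhbb -3.13, Cp -3.09, Arg2 -2.83, Igfbp1 -2.75 and Serpina6 -2.71. Next came D17H6S56E-5 -2.48, Kynu -2.41, Cdkn1a -2.26, 2410006H16Rik -2.14, Fos -1.90, Cxcl1 -1.82, Gldc -1.82, Igfbp2 -1.80, Cd44 -1.79 and Cry1 -1.78. Next came Sgk1 -1.73, Tmem37 -1.72, Fga -1.70, Lyz2 -1.66, Nfil3 -1.64, Gsta2 -1.60, Mgp -1.55, Ccn2 -1.50, Hpd -1.47 and Alas2 -1.44. Next came Dusp1 -1.42, Btg2 -1.39, Slc13a1 -1.39, Egr2 -1.34, Plin4 -1.16, Rgs5 -1.09, Hspb1 -1.04, Vwf -1.04, Acot3 -0.99 and Zfp36 -0.98. Next came Fkbp5 -0.90, Vcam1 -0.81, Rhcg -0.62 and Scnn1a -0.56. The calls of Fkbp5 (adjusted p = 0.0481), Lyz2 (adjusted p = 0.0389), Egr2 (adjusted p = 0.03), Fos (adjusted p = 0.022) and Vwf (adjusted p = 0.0262) ended with quantile normalization, at adjusted p = 0.0584, 0.0559, 0.0588, 0.0874 and 0.0998, and without several single arrays. That of Fkbp5 also ended with array weights (adjusted p = 0.0608) and with the mean of its probe sets (adjusted p = 0.0755). That of Cyp27b1 (adjusted p = 0.0408) ended without any of 9 arrays, and that of Scnn1a without KO ANG II replicate 3 (adjusted p = 0.0502) or WT baseline replicate 3 (adjusted p = 0.0503). Those of Car3 and Slc7a13 ended with the variance trend. None of the 16 list calls held with an estimated correlation. The lists had median differences of -0.81 for tubular injury, -0.77 for immediate early genes, -0.39 for macrophage markers, -0.31 for inflammatory cytokines and adhesion, and -0.29 for podocyte markers. They were -0.23 for vascular cell markers, -0.21 for matrix and fibrosis, and -0.17 each for mineralocorticoid-responsive genes, principal cell markers and interferon-stimulated genes. They were -0.12 each for intercalated cell markers and fatty acid oxidation, and -0.08 for oxidative stress. They were 0.38 for cholesterol synthesis and 0.24 each for proximal tubule markers and oxidative phosphorylation. Among control probe sets, which no comparison used, the hybridisation controls were higher in all 3 KO ANG II arrays than in all 3 KO baseline arrays, by a mean log2 of 0.42. In WT, the Actb, Gapdh and Tfrc controls were lower in all 3 ANG II arrays than in all 3 baseline arrays, by -0.41, -0.17 and -1.41. In KO, the Actb and Gapdh controls and those of B1 and B2 repeats were likewise lower in all 3 ANG II arrays, by -0.25, -0.026 and -0.19. At baseline, controls of 18S ribosomal RNA were lower in all 3 KO than in all 3 WT arrays, by -0.53, as was Tfrc, by -0.44, and those of Actb and of B1 and B2 repeats were higher, by 0.10 and 0.18. Under ANG II the hybridisation, Actb, Gapdh and Tfrc controls were higher in all 3 KO than in all 3 WT arrays, by 0.15, 0.26, 0.14 and 1.43.

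For the difference of the responses, 100 splits regrouped the treatment within each genotype, the real one included. Of these, 2 called as many probe sets as the real 4404. Such splits break up the response of both genotypes, so they cannot test whether the responses are equal, and chance is not excluded. The highest other split called 12327. It turns the treatment labels of a single genotype, so it measures the sum of both responses, a structure of the samples. The next highest splits called 3301, 1863 and 1692. The other comparisons allow 10 splits each, too few for a share under 0.05. In these the real split, the 1 with as large a result, called 10876 probe sets in the WT response against 0 in the highest other, 4465 against 1 in the KO response, 2936 against 0 at baseline and 8934 against 2 under ANG II.

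Camera called macrophage, matrix, injury and immediate early lists higher in KO baseline than in WT baseline kidneys. It called them lower in KO ANG II than in KO baseline kidneys. With an estimated correlation only the injury and immediate early calls at baseline held (camera adjusted p = 0.036 each). The KO baseline arrays enter both comparisons with opposite sign, so mirrored shifts are partly built in. KO baseline was not compared with WT ANG II. Wild-type kidneys labelled as KO are argued against by Sugct and Gpx6, the 2 genes at least 4-fold lower in KO on the baseline arrays: on the infused arrays, which played no part in that choice, all 3 KO arrays lay below every WT array for both. A lower share of tubule cells as the whole cause would raise the macrophage and endothelial lists alike. At baseline the macrophage list lay above the endothelial list by a median log2 of 0.803 (95% bootstrap interval over genes 0.175 to 1.25, 10000 draws). Genes and not kidneys were resampled, so the interval does not measure variation between mice and cannot decide this. Exchanged treatment labels of the KO baseline and KO ANG II groups cannot be told apart from a real difference, because the correlation of the WT and KO responses as labelled, 0.2347 across probe sets, lay between the bounds set for either. A biological effect of the genotype on the baseline kidney stays open and was not tested apart from these.

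Clock genes of the WT baseline kidneys differed from those of the other 3 groups. An index of 12 clock genes, the mean of 5 genes minus that of 7 of opposite daily phase, was -1.19 ± 0.19 (SD, n = 3) in WT baseline, 0.45 ± 0.27 in WT ANG II, 0.13 ± 0.08 in KO baseline and 0.13 ± 0.59 in KO ANG II kidneys. The index of KO ANG II replicate 2 was -0.45. Between KO and WT baseline, Cry1 (log2 change 1.74), Nfil3 (1.29), Nr1d1 (-1.18) and Ciart (-0.77) were called by limma. Dbp (-1.49), Nr1d2 (-0.55), Per3 (-0.24), Tef (-0.23), Hlf (-0.12), Arntl (-0.02), Npas2 (0.09) and Clock (0.24) were not. The index of KO baseline lay above that of WT baseline by 1.321 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Another time of collection for the WT baseline kidneys could give this shift and cannot be told apart from an effect of the groups, since times of collection are not given in the sources used here.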

How the results depend on the processing

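The filter on probe sets of low spread was chosen after the data were seen, as was the exchange of the planned variance trend for none. With the planned trend on the mean ratio the counts were 10975, 4621, 4457, 3032 and 9041 for the WT response, the KO response, the difference, baseline and ANG II, all within 1.5 times of those reported, but 18 of 480 values of named genes lost their call, Car3, Sugct, Gpx6, Acsm3 and Slc7a13 among them. Genes with a large change have an extreme mean ratio, so that trend is not one on intensity. Quantile normalization gave 5704 in the WT response, 2867 for the difference and 4063 under ANG II, and the 2 groups alone gave 4991 under ANG II. Array weights gave 6962 in the KO response and 4849 at baseline. Quantile normalization gives every array the same spread, and spread was widest in the WT ANG II arrays (SD 0.268 to 0.342). It narrows those arrays whether or not their spread came from the infusion. Without these arrays its counts were 4546 in the KO response and 3068 at baseline. Array weights were lowest for WT ANG II replicates 3 and 1, at 0.508 and 0.582. The cause of these changes in the counts was not tested. With 1 probe set per gene 4493, 1928, 1970, 1247 and 4224 genes were called, and with the mean of a gene's probe sets 4821, 2333, 2361, 1469 and 4651, since fewer features were tested. At an unadjusted p under 0.01 and at least 1.5-fold the responses shared 247 probe sets in the same direction, and 41 and 51 in opposite directions. Leaving out 1 array at a time gave 5773 to 12277 in the WT response, 2069 to 4276 in the KO response, 2484 to 5104 for the difference, 1107 to 2338 at baseline and 5021 to 10743 under ANG II, and the group left with 2 arrays shares the spread of the others.

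No value called in the reported fit or in an alternative reversed its direction. For values called in neither, the direction was not compared. Of 3384 values of named genes without 1 array, 2831 kept their side of the threshold, 545 lost and 8 gained a call. With quantile normalization 91 of 480 lost theirs. Of 145 list results 57 lost their call with an estimated correlation, while with fry 11 lost and 19 gained one. Replicate numbers were not taken as pairs, since the correlations of arrays with the same number, after removal of the group means, ran from -0.157 to 0.219, with 7 of 18 over 0.1, and 6 of 12 arrays were closest to their own number. The WT arrays alone differ: their 3 same-number pairs correlated at 0.186, 0.183 and 0.128 and their other pairs at 0.019 or below, while the same-number KO pairs lay at -0.0101 or below. With the replicate number as a block the counts were 11043, 4521, 4276, 2992 and 9180. In the WT response it ended the calls of oxidative phosphorylation and of vitamin D, phosphate and calcium handling (adjusted p = 0.0563 each), and elsewhere those of proximal tubule markers for the difference (adjusted p = 0.0507), S100a8 in KO (adjusted p = 0.0509) and the difference of Fkbp5 (adjusted p = 0.0664), while adrenal markers at baseline gained a call (adjusted p = 0.0398). With probe sets of low spread left out, 22519 were tested and 8733, 3978, 3746, 2947 and 6981 called. The planned filter on dim probe sets was not run, since ratios keep no level, and signal over background is unknown for the same reason.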

Other observations

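The genes of the first 2 paragraphs and the test on Sugct and Gpx6 were chosen after their values were seen, while the test of all baseline genes by chromosome was not. Kidney genes known to differ in expression between male and female mice were looked up singly, with no list set in advance and no test of them as a group. In WT kidneys Slc7a13 fell by 2.47 on the log2 scale, Acsm3 fell by 2.41, Slco1a1 fell by 2.19, Slc22a30 fell by 1.90, Cyp2j13 fell by 1.60 (adjusted p = 0.000117), Odc1 fell by 1.42, Cyp4a12a fell by 1.01 (adjusted p = 0.000546) and Cyp7b1 fell by 0.45 (adjusted p = 0.025). In the same kidneys Kap, a classic gene of this kind, had a log2 change of -0.09 ± 0.07 (adjusted p = 0.376), Hsd11b1 of -0.10 ± 0.16 (adjusted p = 0.65), Cyp2e1 of 0.09 ± 0.10 (adjusted p = 0.498) and Slc7a12 of -0.00 ± 0.51 (adjusted p = 0.997), none called. The calls of Slc7a13 (adjusted p = 0.0562) and Acsm3 (adjusted p = 0.107) ended with a trend of the variance on the mean ratio. In KO kidneys Odc1 rose by 1.31, Hsd11b1 rose by 0.66 (adjusted p = 0.0173) and Slc7a12 fell by 2.21 (adjusted p = 0.016, and adjusted p = 0.0633 without KO baseline replicate 2). The others were not called in KO, namely Slco1a1 (0.49), Cyp2j13 (0.49), Cyp4a12a (0.42), Slc22a30 (0.38), Acsm3 (0.28), Slc7a13 (0.16), Cyp2e1 (0.16), Kap (0.02) and Cyp7b1 (-0.25). The responses differed between the genotypes by 1.42 for Cyp4a12a (adjusted p = 0.00116), 2.73 for Odc1 and 0.77 for Hsd11b1 (adjusted p = 0.0422). Those of Cyp7b1 and Slc7a12 differed by 0.20 ± 0.18 (adjusted p = 0.571) and -2.21 ± 0.72 (adjusted p = 0.0705) and were not called. The responses of Kap and Cyp2e1 differed by 0.12 ± 0.10 and 0.07 ± 0.14 and were not called either.

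In WT kidneys 3 genes known to act in iron or heme handling were called. The transferrin receptor gene Tfrc fell by 1.41 (adjusted p = 0.000147), while Alas2, which starts heme synthesis, rose by 1.38 and Hmox1, which degrades heme, rose by 2.64. Hamp, the gene of an iron hormone, had a log2 change of 0.22 ± 0.13 in WT and was not called (adjusted p = 0.202). In KO kidneys Tfrc had a log2 change of 0.25 ± 0.17 and Alas2 one of -0.05 ± 0.16, neither called, and the responses differed by 1.66 ± 0.24 and -1.44 ± 0.23. At baseline the B cell surface genes Cd79a, Cd79b and Ms4a1 differed between the genotypes by 0.03 ± 0.09, 0.05 ± 0.16 and 0.00 ± 0.16, and 1 of the 11 probe sets of Ighm by 0.15 ± 0.10, none called, beside the higher Jchain, Igha and Igkv8-30 of KO kidneys.

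Genes that differ between KO and WT may stem from 129 or C57BL6 DNA that flanks the targeted gene. For the baseline differences as a whole the data argue against this, as 43 of 1188 called genes lay on the chromosome of Agtr1a against 702 of all 18029 placed genes (odds ratio 0.9222, 95% interval 0.657 to 1.26, Fisher's exact p = 0.698). The genes at least 4-fold lower in KO in both states, Sugct and Gpx6, were 2, and both lay on that chromosome, 91 and 73 measured genes from Agtr1a in assembly GRCm38.p6. Since this rule was set after both genes had been seen, it does not test flanking DNA, which for this pair cannot be told apart from an effect of the receptor.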
